A study of Mus musculus with 2 samples.

How the data were processed

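H3K36me3 was measured by chromatin immunoprecipitation and sequencing in 2 biological replicates of hindbrain from mouse embryos at embryonic day 11.5, strain B6NCrl. Per the labels, replicate 1 pooled 109 embryos and replicate 2 pooled 88 embryos, both sexes were mixed, library fragments were 300 to 500 bp, and each replicate had 3 technical replicates. Both replicates form 1 group, so no groups were compared and the spread is that between 2 tissue pools.

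The authors deposited a peak list per replicate and 2 lists for the whole series, all on the mouse build mm10 (GRCm38). Per the file listings deposited with the samples, each replicate's peaks were called on its own alignments with technical replicates together, a further list was called on the alignments of both replicates pooled, and a replicated list was derived from these. The peak caller, its version, the aligner and the threshold are not given in the sources used here. Each peak has a score that the authors deposited as a whole number up to 1000, and it was used to rank peaks within a list. The signal per peak is the authors' enrichment value, whose reference is not given in the sources used here. The authors deposited a −log10 p-value and a −log10 q-value per peak, which were used as thresholds within a list. The weakest peaks had a −log10 p of 2.01 in replicate 1, 2.06 in replicate 2 and 2.04 in the pooled list. A −log10 q of at least 2 was reached by 47565 peaks in replicate 1 (52.5%), 27466 in replicate 2 (38.5%) and 5358 in the pooled list (12.4%), and the other peaks had weaker evidence. Since read counts were not used here, depth is unknown, and the precision of a value rests on the spread between the replicates.

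Peaks were placed on GENCODE mouse release M21 and the GRCm38 sequence. No peak passed a chromosome end and none lay inside an assembly gap. Chromosomes 1 to 19, X and Y were analysed, and 36 peaks of each replicate on scaffolds outside the assembled chromosomes were left out. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9, with fixed random seeds.

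Overlap meant at least 1 bp. It was tested, one-sided, against 1000 circular rotations of the replicate 2 list within each chromosome, which keep peak sizes and spacing. Ties in score were broken at random when peaks were split into 5 equal groups. Each base was given 1 annotation class in this order: within 1 kb of a start of a protein-coding gene, coding exon, untranslated exon, other exon, intron, 5 kb past a gene end, other intergenic. Shares of peak bases were divided by shares of the genome and tested, two-sided, with 1000 rotations. A gene body ran from annotated start to end, and a gene was marked when at least 10% of it lay under peaks in both replicates. The body profile used 10 equal bins of marked genes of at least 10 kb. The exon to intron comparison used exons of protein-coding transcripts and the sequence between them in marked genes with at least 2 exons. Covered bases and lengths were summed over genes before each ratio was taken. Intervals of both ratios are 95% ranges of 1000 bootstrap draws of chromosomes. Overlapping genes each receive the peaks they share, which the lists, having no strand, cannot divide.

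The 25 gene lists, the design, the rule for named genes and the alternatives were chosen before the data were examined, except the alternatives with random lists matched on GC content as well and with genes overlapping no other protein-coding gene, which were added afterwards. Each list's mean coverage was set, two-sided, against 10000 random lists of the same size drawn with replacement from protein-coding genes in 20 bins of gene length, with Benjamini-Hochberg adjustment over the 25 lists. This permutation test compares genes within these libraries and is not a test between conditions. Of the listed symbols, 16 of 35 for histone, 27 of 33 for olfactory receptor, 28 of 34 for imprinted and 25 of 26 for long neural genes were matched to protein-coding genes. Those of the other lists were matched in full. The histone, olfactory receptor and long neural lists mix older and newer symbols, so an unmatched symbol is not always an unmeasured gene. Named genes are the members of each list with the largest and smallest coverage (up to 4), the 10 genes with the most covered bases, the 10 genes of at least 20 kb with the largest percent covered (both by the lower replicate), the 5 genes of at least 10 kb with the widest gap between replicates in each direction among those marked in 1 replicate, the 5 highest-scoring replicated peaks and the 5 longest shared intergenic regions.

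The steps were tested on simulated data. In random lists of the replicates' sizes, with peaks copied from 1 list to the other, 41.1% overlapped where copies and rotated overlap gave 41.2%. Of 20 pairs of unrelated lists, 1 had a p under 0.05. An enrichment of 3-fold in introns gave 2.97, a downstream to upstream ratio of 2 gave 1.98, and an exon to intron ratio of 2 gave 1.98. The exon to intron simulation placed points of 1 bp at the same density in every gene. Effects of peak width and of differences between genes were thus not covered. Of 100 random lists of 25 genes, 3 had a p under 0.05, and 65% of lists with coverage doubled and 100% of those with coverage multiplied by 4 were recovered, so lists that differ by a factor near 2 can be missed.

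Alternatives comprised peaks with a −log10 q of at least 2 or a −log10 p of at least 5, equal numbers of peaks per replicate, peaks merged within 1 kb, each replicate alone, the authors' combined lists, overlaps of 50%, other annotation windows, other gene selections and other marking levels, with 200 rotations each.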

Results

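H3K36me3, the trimethylation of lysine on histone H3 that is laid down in the wake of elongating RNA polymerase, was mapped by chromatin immunoprecipitation and sequencing in hindbrain of mouse embryos at embryonic day 11.5. The 2 biological replicates each pooled tissue of many embryos of both sexes, 109 embryos in replicate 1 and 88 in replicate 2, and they form 1 group. No other tissue, stage or input library was part of the comparisons, so each result sets genes or regions against others within these 2 libraries. Replicate 1 had 90644 peaks covering 27.4 Mb (1.00% of the genome) and replicate 2 had 71344 peaks covering 21.4 Mb (0.786%). Median peak width was 244 bp and 247 bp. The lists carry no read counts, so the sequencing depth behind a peak is unknown. In replicate 1, 7977 peaks shared 1 identical p, and 6672 did so in replicate 2, so many peaks cannot be ranked by p.

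The highest-scoring peaks of the authors' replicated list lay over coding exons of Mid1, of the zinc finger genes Zfp354c, Zfp606 and Zfp810, and of Srrm2, which encodes a splicing factor. The scores are theirs and rank peaks within that list alone, in which the Mid1 peak had the highest score, 1000 (chromosome X, 169988507 to 169989472, mm10). Zfp354c followed with 616 (chromosome 11, 50813732 to 50818064), Zfp606 with 506 (chromosome 7, 12493088 to 12494409), Zfp810 with 459 (chromosome 9, 22278093 to 22279330) and Srrm2 with 457 (chromosome 17, 23815129 to 23821445). Peaks were not screened for repeated sequence here, and the placing of reads at the Mid1 peak was not tested. The first question was how far the replicates marked the same places. Of the replicate 1 peaks on assembled chromosomes, 36.8% overlapped a replicate 2 peak by at least 1 bp, and 46.7% of replicate 2 peaks overlapped one of replicate 1. After circular rotation of 1 list within chromosomes the mean shares were 1.77% and 2.24%, and the highest of 1000 rotations reached 3.39% and 4.27% (one-sided rotation permutation test, p = 0.001, the smallest these rotations can give). The Jaccard index of covered bases was 0.188, against a mean of 0.0053 after rotation. Rotation also moves peaks off genes, so it cannot separate sharing of the same genes from sharing of positions within them. Overlap was higher for peaks with higher scores: of 5 equal groups by score, group 1, the lowest, overlapped the other list in 25.6% of peaks and group 5 in 57.7% in replicate 1, and in 35.3% and 66.0% in replicate 2.

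**Figure D1:**
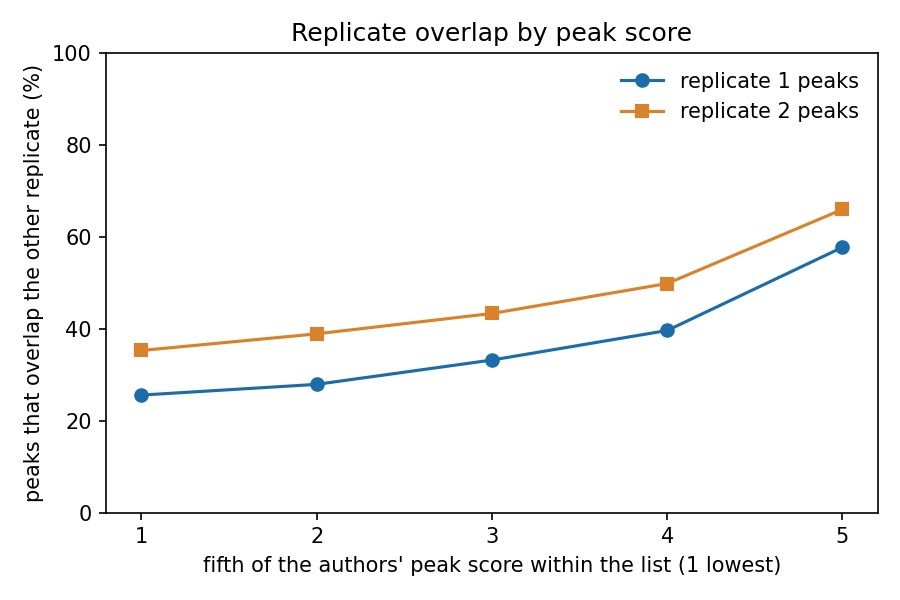
Percent of each replicate's peaks (y axis, %) that overlap the other replicate's list by at least 1 bp, in 5 equal groups by the authors' peak score within the list (x axis, 1 lowest). Circles stand for replicate 1 and squares for replicate 2, and the share goes from 25.6% to 57.7% and from 35.3% to 66.0% between groups 1 and 5.

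The authors' combined lists held fewer peaks than either replicate. Their list called on both replicates together had 43249 peaks, and their replicated list had 34245, every one of which is also a line of the pooled list. Of the replicated peaks on assembled chromosomes, 92.4% overlapped replicate 1, 86.7% overlapped replicate 2 and 79.1% overlapped both. Of the pooled peaks, 64.9% overlapped both replicates.

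Peaks lay within genes, and by share of the genome coding exons were the most enriched class. Coding exons held 15.1% ± 0.636 of peak bases (SD, n = 2) but 1.21% of the genome, an enrichment of 12.4-fold ± 0.524. Exons of untranslated regions were enriched 5.75-fold ± 0.0266 and exons of other genes and transcripts 3.64-fold ± 0.0376. Introns held most of the peak bases, 64.8% ± 0.393, against 39.6% of the genome (1.64-fold ± 0.0099). Windows of 1 kb on either side of transcription start sites of protein-coding genes were depleted, with 0.592% ± 0.0330 of peak bases against 1.52% of the genome (0.390-fold ± 0.0218). The 5 kb past gene ends were covered at 0.674-fold ± 0.0014, and the remaining intergenic sequence, 48.9% of the genome, held 1.69% ± 0.236 of peak bases (0.0346-fold ± 0.0048). Each of the 7 classes departed from rotated peaks in the same direction in both replicates (two-sided rotation permutation test, p = 0.002 in each, the smallest that 1000 rotations can give). The classes within genes and start windows together held 94.5% ± 0.244 of peak bases and 45.4% of the genome.

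**Figure D2:**
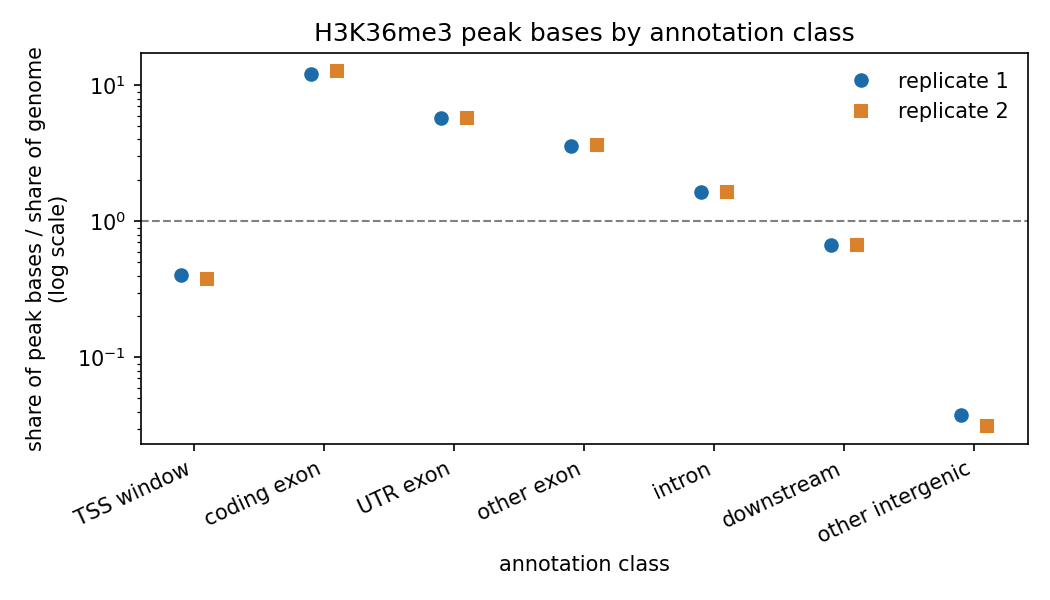
Share of H3K36me3 peak bases divided by share of the genome (y axis, log scale) for 7 annotation classes (x axis), with circles for replicate 1 and squares for replicate 2. The dashed line marks equal shares, coding exons lie highest at 12.1 and 12.8, and other intergenic sequence lies lowest at 0.0380 and 0.0311.

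Coverage was lowest at the start of genes and highest near their ends. Over 1774 marked protein-coding genes of at least 10 kb, the first of 10 equal bins of the gene body had 3.19% ± 0.418 of its bases under peaks (SD, n = 2), bin 5 had 19.8% ± 2.54, bin 9 had 28.1% ± 2.92 and bin 10 had 25.9% ± 2.87. The downstream part of these genes, bins 6 to 10, was covered 1.92 times as much as bins 1 to 5 in replicate 1 (95% interval 1.86 to 1.98 over chromosomes) and 1.97 times as much in replicate 2 (1.89 to 2.05). Summed over marked genes, exon bases were more covered than intron bases, and exons were not compared with introns gene by gene. In 2385 marked genes with at least 2 exons, 31.9% of exon bases and 18.9% of intron bases lay under replicate 1 peaks, a ratio of 1.69 (1.65 to 1.72). In replicate 2 these were 27.7% and 15.8%, a ratio of 1.75 (1.70 to 1.79).

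**Figure D3:**
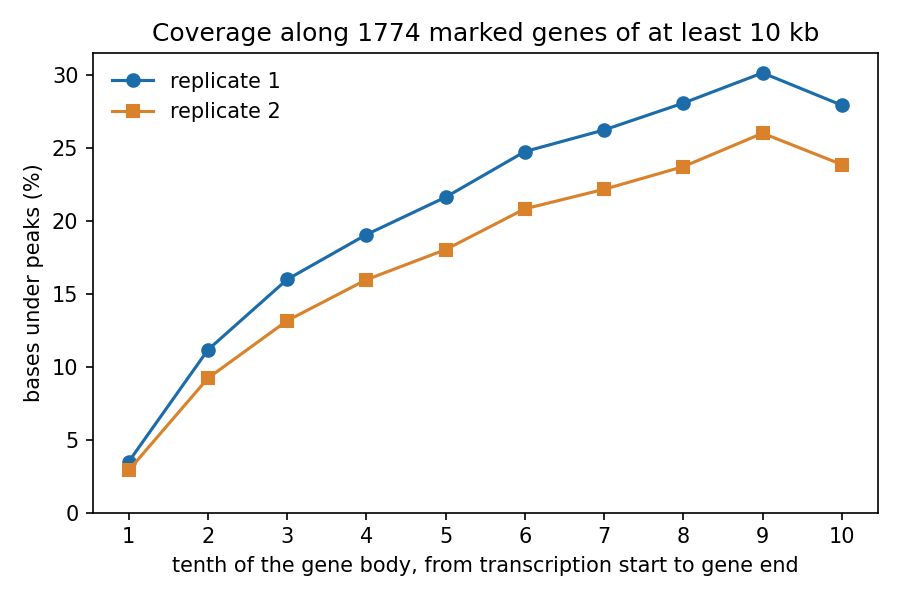
Percent of bases under peaks (y axis, %) in each of 10 equal bins of the gene body from transcription start to gene end (x axis) over 1774 marked protein-coding genes of at least 10 kb. Circles and squares are replicates 1 and 2, whose mean goes from 3.19% in bin 1 to 28.1% in bin 9.

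Among protein-coding genes of at least 20 kb, the most fully covered included regulators of transcription and chromatin. Tcf3, a transcription factor of the E protein family, had 51.1% ± 5.46 of its body under peaks (SD, n = 2; chromosome 10, 80409514 to 80433647), the histone methyltransferase gene Kmt2d 48.8% ± 7.31 (chromosome 15, 98831669 to 98871204), and Chd4, which encodes a chromatin remodeller, 45.6% ± 1.06 (chromosome 6, 125095981 to 125130591). Prr12 had 50.3% ± 10.8, Safb2 48.6% ± 2.22, the cell polarity gene Scrib 47.4% ± 8.31, the nuclear import gene Kpnb1 46.3% ± 3.80, Zfp810 46.2% ± 3.71, the dynein heavy chain gene Dync1h1 44.9% ± 3.81 and the splicing gene Rbm5 43.8% ± 3.30. By the number of covered bases, Ubr4, a ubiquitin ligase gene, had 41145.5 bp ± 3925 and Trrap, part of histone acetyltransferase complexes, 35558 bp ± 2836. Wdfy3, Syne2, Macf1, Chd2, Dync1h1 and Eif4g3 had between 28227 bp (Eif4g3) and 33190.5 bp (Wdfy3). Gm20388 and Fgfr2 also ranked among the top 10, but their annotated spans, 4434882 bp and 2960900 bp, run across many other protein-coding genes, and 3.11% ± 0.572 and 1.56% ± 0.465 of these spans were covered.

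A gene was called marked when at least 10% of its body lay under peaks in both replicates. Of 21938 protein-coding genes, 3504 passed this level in replicate 1, 2745 in replicate 2 and 2420 (11.03%) in both, where 438 would do so if the replicates were independent. A peak of any size was present in both replicates in 8944 genes, and 10276 genes had none in either. The 1084 genes past the level in replicate 1 alone had a median of 12.8% there and 7.13% in replicate 2, and the 325 in replicate 2 alone had 12.7% there and 6.85% in replicate 1. Among such genes of at least 10 kb, the widest gaps were at Vps9d1, with 32.6% in replicate 1 and 8.83% in replicate 2, followed by Gm49369, D11Wsu47e, Xrcc3 and 4833439L19Rik. In the other direction, within the same length limit, they were at Vezf1, with 8.75% and 23.2%, followed by Glrx5, Dcaf11, Zfp40 and Dimt1. The count of marked genes depended on the level: 8944 genes had any peak and 407 had at least 25% of the body covered in both replicates, while 1008 passed 10% with peaks at a q of 0.01 or below. Of 5 equal groups by gene length, the shortest had 5.22% of genes marked, group 3 (11963 bp to 25134 bp) 18.98% and the longest, from 58120 bp up, 3.37%. With any peak as the criterion the longest group had the highest share, 61.5%, and the shortest the lowest, 10.2%.

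The gene lists asked which kinds of genes carried the mark in this tissue. Of 25 lists, 7 were more covered than random lists of genes of matched length, 13 were less covered and 5 did not pass the test. RNA processing and splicing genes were the most covered list, with 26 of 30 members marked and a mean of 23.3% ± 2.34 of the body under peaks (SD, n = 2), against 4.93% in random lists. Prpf8, the core protein of the spliceosome, had 48.8% ± 11.7 and the spliceosomal helicase gene Snrnp200 39.3% ± 2.66, while Dhx15 had 4.15% ± 0.760 and Ptbp2, the neural splicing regulator, 3.12% ± 0.160. Ribosomal protein genes had 18 of 32 marked and a mean of 18.7% ± 6.12 against 3.16%, from Rps3 (49.9% ± 14.8) and Rpsa (36.9% ± 13.0) to Rpl15 and Rps23 with no peak. This list differed most between replicates, with 23.0% in replicate 1 and 14.4% in replicate 2. Cell cycle and DNA replication genes had 20 of 30 marked and a mean of 16.8% ± 1.32 against 4.75%. Cdk4 (49.98% ± 7.95), which shares bases with Tspan31, and the mitotic kinase gene Cdk1 (27.3% ± 3.43) led this list, and Pcna (2.62% ± 3.71) and Pola1 on chromosome X (0.0895% ± 0.127) were lowest. Housekeeping genes had 9 of 26 marked and 12.4% ± 1.25 against 4.58%, led by the translation elongation factor gene Eef2 (49.7% ± 4.89) and the chaperone gene Hsp90ab1 (35.1% ± 3.47), with none at B2m and Tuba1b. All of these lists, and the 3 described next, had a Benjamini-Hochberg adjusted p of 0.000417 in a two-sided permutation test against 10000 random lists, the smallest the test gave. At a level of 25% of the body covered, which 407 genes passed, RNA processing was the 1 list still called above random lists. So few genes leave no room for a list of this size to fall below.

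Genes of the methylation system itself, of zinc finger repressors and of neural progenitors were the other lists above random. Of 24 writers, erasers and readers of H3K36 methylation 9 were marked, with a mean of 11.4% ± 1.46 against 3.77%. Kdm4a, a histone demethylase gene, had 42.2% ± 4.13 (chromosome 4, 118136957 to 118180043) and Brpf1 32.2% ± 4.77, whereas Kdm4c had 0.756% ± 0.486 and Phf19 no peak. KRAB zinc finger genes, repressors of transposable elements, had 21 of 84 marked and a mean of 10.2% ± 1.16 against 5.45%. Zfp90 had 61.5% ± 2.62 (chromosome 8, 106415327 to 106426598) and Zfp68 58.8% ± 7.24, and 21 members, Zfp951 and Zfp953 among them, had no peak in either replicate. Neural progenitor genes had 9 of 27 marked and a mean of 9.24% ± 1.27 against 3.11%. Msi1, an RNA-binding protein of neural stem cells, had 35.5% ± 8.04 (chromosome 5, 115429599 to 115455698) and the receptor gene Notch1 26.8% ± 4.83 (chromosome 2, 26457903 to 26516663), and the transcription factor genes Sox2 and Sox3 had none.

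**Figure D4:**
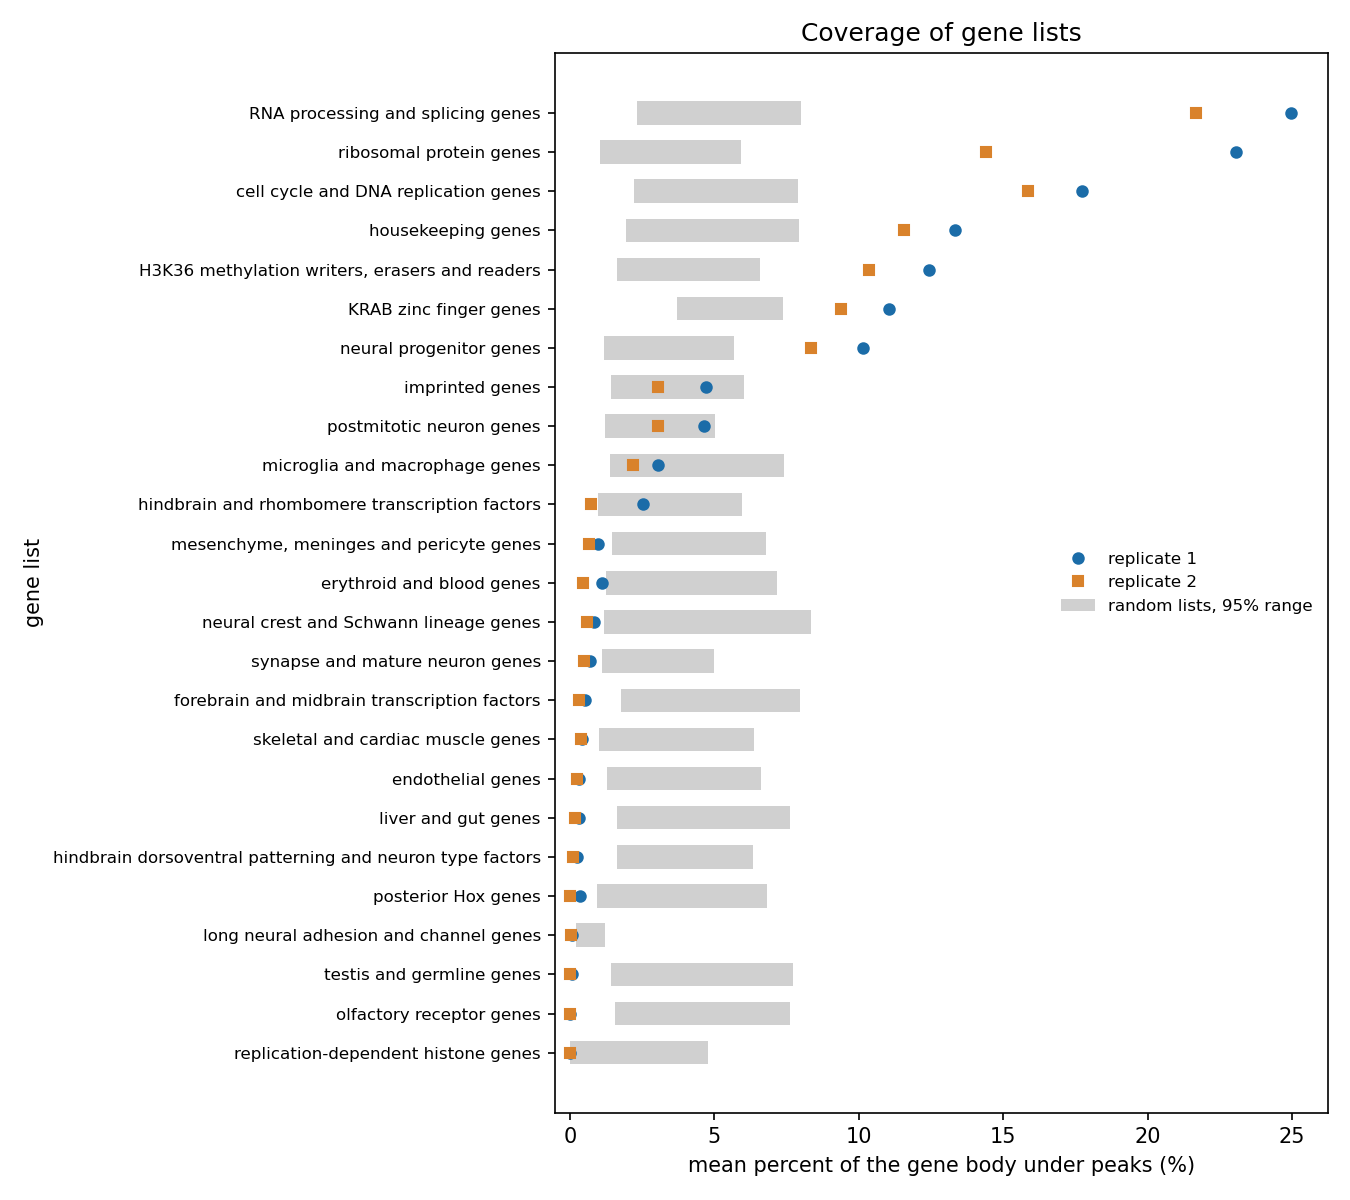
Mean percent of the gene body under peaks (x axis, %) for each of 25 gene lists (y axis), with circles for replicate 1 and squares for replicate 2. Grey bars span the central 95% of 10000 random lists matched on gene length, and 7 lists, from neural progenitor genes at 9.24% to RNA processing genes at 23.3%, lie to their right.

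Transcription factors that pattern the hindbrain were little covered. None of 36 dorsoventral patterning and neuron type factors was marked, and their mean was 0.179% ± 0.105 against 3.70% in random lists (adjusted p = 0.000417, permutation). Pax3, the dorsal patterning factor, had the most, 1.36% ± 0.623, followed by Lhx1 (1.28% ± 1.81), and Tlx3 and Zic4 had none. The list of hindbrain and rhombomere transcription factors also holds Fgf3 and Epha4, which do not encode transcription factors. It had none of 25 members marked and a mean of 1.63% ± 1.25 against 3.06%, which did not pass the test (adjusted p = 0.288, permutation). In this list Irx2 had 11.5% ± 7.70 and Irx3 6.92% ± 9.78, with no peak of replicate 2 in Irx3, and Hoxd4 and the rhombomere factor Mafb had none. Forebrain and midbrain factors had 0 of 26 marked and 0.414% ± 0.157 against 4.48% (adjusted p = 0.000769, permutation), with the most in Bcl11b (3.08% ± 0.0334). Posterior Hox genes had 0 of 24 and 0.176% ± 0.249 against 3.42% (adjusted p = 0.00333, permutation). When members within 100 kb of each other were counted once, which leaves fewer genes, the mean was 0.0807% and this call ended (adjusted p = 0.0595, permutation; 0.000417 to 1 over the alternatives).

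Postmitotic and synaptic genes were measured as separate lists, and the difference between the lists was not tested. Of 30 postmitotic neuron genes 4 were marked, and the mean of 3.86% ± 1.13 against 2.87% did not pass the test (adjusted p = 0.337, permutation). The microtubule regulator genes Stmn1 (19.2% ± 5.44) and Map1b (15.03% ± 0.40) led, and Celsr3 (14.1% ± 5.18) and Crmp1 (13.0% ± 0.745), named here after their values were seen, were the other marked members. Synapse and mature neuron genes had 0 of 25 marked and 0.593% ± 0.162 against 2.76% (adjusted p = 0.00406, permutation), with the most in Dlg4 (4.41% ± 2.83) and none in Pvalb or Scn1a. Long neural adhesion and channel genes had 0 of 25 marked and 0.0494% ± 0.0134 against 0.575% (adjusted p = 0.000417, permutation), though 15 of the 25 had a peak in both replicates. With any peak as the criterion, neither of these last lists passed the test (adjusted p = 0.450 and 1, permutation; 0.00176 to 1 and 0.000417 to 1 over the alternatives).

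Markers of other cell types that dissected hindbrain can hold were below random lists in most cases. Endothelial genes (0 of 22 marked, 0.294% ± 0.0477 against 3.58%, adjusted p = 0.00107), mesenchyme, meninges and pericyte genes (1 of 23, 0.833% ± 0.223 against 3.76%, adjusted p = 0.00588) and erythroid and blood genes (0 of 23, 0.788% ± 0.464 against 3.75%, adjusted p = 0.0118) were less covered by the permutation test. The marked mesenchymal gene was Fn1, which encodes fibronectin, with 13.1% ± 2.40. Neural crest and Schwann lineage genes had 0 of 16 marked and 0.721% ± 0.165 against 4.21% (adjusted p = 0.0175, permutation). Muscle genes (0 of 22, 0.404% ± 0.0329 against 3.26%, adjusted p = 0.00667) and liver and gut genes (0 of 25, 0.237% ± 0.105 against 4.24%, adjusted p = 0.000417) were lower too in this permutation test. Microglia and macrophage genes had 1 of 22 marked and 2.61% ± 0.606 against 3.95% (adjusted p = 0.418, permutation). That gene was Cd68 (46.4% ± 14.5), whose start lies 782 bp past the end of Eif4a1, a translation initiation factor gene on the same strand with 26.4% and 27.4% covered in replicates 1 and 2. With any peak as the criterion, the erythroid and neural crest calls ended (adjusted p = 0.255 and 0.0797, permutation; 0.00805 to 1 and 0.00115 to 1 over the alternatives).

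Olfactory receptor genes had no peak in any of 27 members in either replicate, against a mean of 4.22% in random lists, and testis and germline genes had 0 of 22 marked and 0.0406% ± 0.0575 against 4.09% (adjusted p = 0.000417 each, permutation). Histone genes that are transcribed with DNA replication had no peak in 16 measured members. Random lists of such short genes averaged 1.33% and their 95% range reached 0, so this did not pass the test (adjusted p = 0.331, permutation). Imprinted genes had 1 of 28 marked and 3.88% ± 1.16 against 3.40% (adjusted p = 0.636, permutation). The marked gene was Nnat, with 39.9% ± 16.9, which lies inside Blcap, and the retrotransposon-derived gene Rtl1 had 12.2% ± 7.22.

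Chromosome X had a far lower share of marked genes, and far fewer called peaks per Mb, than any autosome. On chromosome X 5 of 948 protein-coding genes were marked (0.527%), against 7.21% on chromosome 14, the lowest autosome, and 16.7% on chromosome 5, the highest. The 5 were Hcfc1, Flna, Maged1, Kdm5c and Gm21887, named after their values were seen. Maged1 had 29.4% and 12.5% of its body covered in replicates 1 and 2, and Flna, the filamin A gene, 18.97% and 10.05%. With any peak as the criterion the share on chromosome X was 9.28%, against 34.3% to 51.4% on the autosomes. Chromosome X had 3.31 peaks per Mb in replicate 1 and 1.90 in replicate 2, where the autosomes had 22.4 to 62.4 and 17.3 to 48.7. Taken singly, the replicates had 1.69% and 0.633% of X genes past the level, against autosomal medians of 16.7% and 12.7%. Both replicates pooled male and female embryos.

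**Figure D5:**
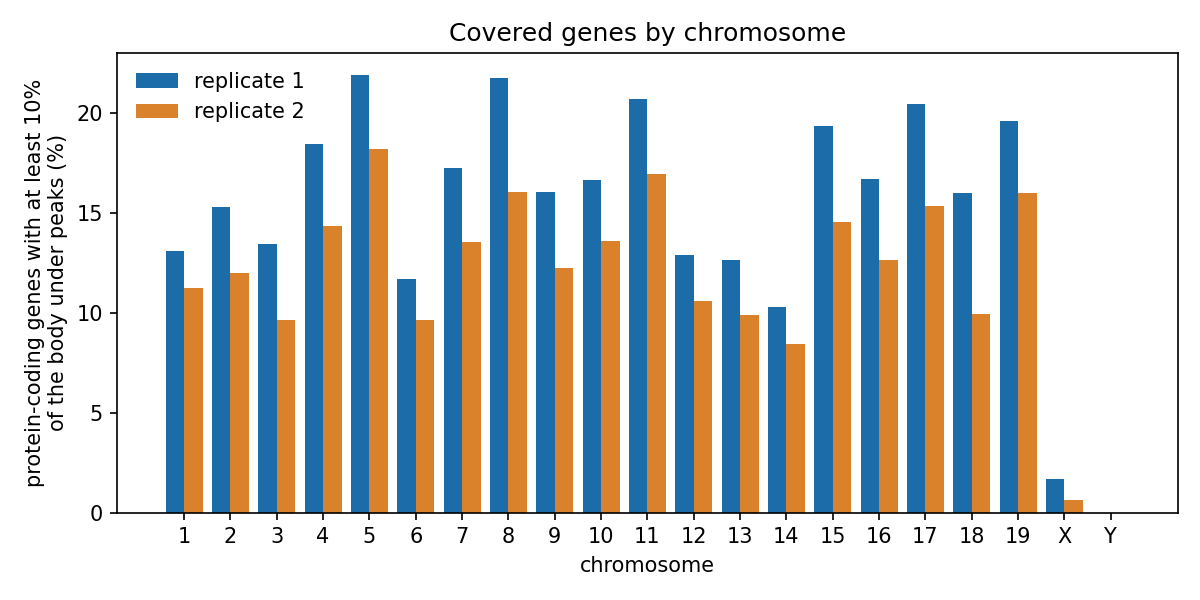
Percent of protein-coding genes with at least 10% of the body under peaks (y axis, %) on each chromosome (x axis), as bars for replicate 1 (left) and replicate 2 (right). Chromosome X stands at 1.69% and 0.633%, below every autosome, of which the lowest, chromosome 14, has 10.3% and 8.43%.

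Few shared peaks lay away from genes. Of replicate 1 peaks that overlapped replicate 2, 44 of 33344 (0.132%) lay over 5 kb from any annotated gene, and 49 of 33271 (0.147%) in replicate 2. Of those within 50 kb of a gene, 26 lay past the end and 15 before the start of the nearest gene in replicate 1, and 32 and 14 in replicate 2. The longest such shared region, 1639 bp, lay 11641 bp past the end of 2610008E11Rik (chromosome 10, 79051094 to 79052732). The next lay past the ends of Dyrk1b (1521 bp, chromosome 7) and, after one on chromosome Y before the start of the pseudogene Mid1-ps1 (1227 bp), Ybx1 (938 bp, chromosome 4), and the fifth before the microRNA gene Gm27878 (830 bp, chromosome 4).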

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

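The tests of members of covered lists and of halved signal on chromosome X, and of the p cutoff and of evidence in the pooled list, were chosen only after the results, or values bearing on them, were seen, and the order of tied scores was changed after a first result.

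Peaks lay on scaffolds outside the assembled chromosomes, sequence that the comparisons left out. There were 36 such peaks in replicate 1 and 36 in replicate 2 (a count of 0 allows up to 3). The lists hold no background for these scaffolds, so whether the peaks exceed one was not tested. They lay on 12 and 11 scaffolds, 11 of them in both replicates, and 17 of the replicate 1 peaks overlapped a replicate 2 peak.

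Chromosome X had 0.527% of its genes marked, and autosomal gene sets matched to its genes on length and GC content had a mean of 7.36% and a lowest value of 4.32% in 10000 sets, which argues against length and GC content as the whole cause. Little use of X genes in this tissue was set against the lists covered above random. In these, 2 of 5 X members (40%) had a peak in both replicates, against 211 of 248 autosomal members (85.1%, two-sided Fisher's exact p = 0.0293). The test rests on 5 genes (Hprt, Sox3, Pola1, Rps4x and Pgk1). The lists were selected for high coverage in the same peaks and their members are mostly autosomal. That selection raises the autosomal share, so the test cannot decide. For a cutoff on weak peaks, density on chromosome X was at most 0.109 of the autosomal density in the weakest of 5 score groups. This lay under the bound of 0.25 set beforehand. The ratio was 0.0623 and 0.0496 in the strongest group and highest in group 2, at 0.123 and 0.0843. Every listed peak had passed the cutoff, so X peaks lost below it are missing from each group and this test cannot decide. A deposited signal halved at every X peak is argued against. Above the autosomal 80th percentile of signal, X peaks had 0.0616 (95% Poisson interval 0.0490 to 0.0765) and 0.0506 (0.0375 to 0.0667) of the autosomal density. Halved autosomal signals give 0.0023 and 0.0011. How the deposited signal scales with the mark is not known, so lower dosage of chromosome X in pools of both sexes stays open and untested, as does the placing of reads on this chromosome.

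Pooled over marked genes, exons were more covered than introns. The ratios were 1.73 and 1.80 over unmatched windows and 1.69 and 1.75 over whole exons and introns. Over windows matched on GC content the mean ratio was 1.67 (95% intervals 1.61 to 1.68 and 1.66 to 1.75), and over windows matched on position along the gene it was 1.46 (1.39 to 1.48 and 1.43 to 1.54). Matched on both, the ratios were 1.35 (1.31 to 1.38) and 1.38 (1.33 to 1.43). Position and GC content thus took part of the pooled difference, and neither alone was its whole cause. Windows were not matched on gene, so how far differences in coverage between genes add to these ratios was not tested. No biological explanation was tested.

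The authors' pooled list had 43249 peaks, fewer than either replicate. A stricter cutoff on p is argued against by its weakest peak, with a −log10 p of 2.04 beside 2.01 and 2.06 in the replicates. Pooling that brought no gain in evidence is a candidate explanation: over 28039 pooled peaks that overlap both replicates, the median −log10 p was 4.16, against 5.73 and 5.50 for the strongest replicate peaks they overlap, a choice of the strongest that favours the replicates. Loss of peaks seen in 1 replicate alone cannot be told apart as the cause, since 86.4% of shared replicate 1 peaks overlapped a pooled peak, between the bounds set for and against it, and 14.5% of the others did. No biological explanation was tested.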

How the results depend on the processing

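The alternatives that match random lists on GC content as well as length, or that keep genes overlapping no other protein-coding gene, were chosen after seeing the data.

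Overlap of the replicates stayed above rotated lists under each of 6 alternatives, at 17.6% to 39.8% of replicate 1 peaks and 22.4% to 46.9% of replicate 2 peaks (rotation permutation p = 0.00498, the smallest that 200 rotations can give). Enrichment kept its direction under each of 11 alternatives in coding exons (11.4 to 16.9), introns (1.52 to 1.68), start windows (0.258 to 0.627) and other intergenic sequence (0.00275 to 0.0380). The downstream to upstream ratio ranged from 1.96 to 2.21 and the exon to intron ratio from 1.61 to 1.87.

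Marked genes numbered 1008 with peaks at a −log10 q of at least 2, 929 at a −log10 p of at least 5, 8944 with any peak and 407 with 25% of the body covered, by construction from fewer peaks or other levels. Among genes with no other gene within 5 kb, 291 of 5674 were marked (5.13%, against 11.03% of all), and the cause of the lower share was not tested. With any peak, 10.2%, 47.6% and 61.5% of the shortest, middle and longest genes were marked and 9.28% of those on chromosome X; at 25% of the body the length groups had 1.07%, 3.71% and 0.251%. At 25% of the body, 1 list was called above random lists (RNA processing) and 0 below, by construction, since 407 marked genes leave lists of about 25 genes with no room to fall below. The lists that lost the call above had 11.5% (housekeeping), 9.52% (KRAB zinc finger), 9.38% (ribosomal), 8.33% (H3K36 methylation), 3.70% (neural progenitor) and 3.33% (cell cycle) of genes marked.

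Overlap with both replicates fell to 76.3% and 53.4% of the replicated list, and to 60.4% and 42.3% of the pooled list, when 50% of either or of both peaks had to be shared, by construction of the stricter overlap. Shared peaks far from genes made up 0.101% (q), 0.119% (p), 0.116% (equal numbers of peaks), 0.181% (peaks merged), 0.126% (replicated list) and 0.0600% (over 10 kb), and 1.80% to 2.27% without replicate 1 or 2, where no peak can be shared and all peaks count. The cause was not tested for the other settings.

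Of the comparisons of single lists, 324 had the same call, 24 lost it and 2 gained it. Hindbrain and rhombomere factors fell below random lists when GC content was matched as well (adjusted p = 0.0317, permutation; up to 1 over the alternatives), and histone genes did without matching on length (0.000417, up to 1). Of the values of named genes, 806 stayed within the spread between replicates and 226 moved by more. A value from 1 replicate alone stays within that spread by construction, as does a value of 0 under stricter peak filters. The count of 806 is therefore no measure of stability. No tested overlap, annotation class or gene list changed direction. The order of the gene length groups did. At 10% of the body the longest genes had the lowest share marked, 3.37%, against 5.22% of the shortest. With any peak the longest genes had the highest share, 61.5%, and the shortest the lowest, 10.2%. Depth, unknown from peak lists, limits how far peaks missed in 1 replicate can be read.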

Other observations

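The 11 gene lists and the noncoding genes below were chosen after the coverage of genes had been seen. The prediction for last exons was written before its test was run. It was not part of the design chosen before the data were examined. The later lists hold genes already seen to be highly covered, such as Kmt2d, Chd4, Trrap, Kpnb1 and Dync1h1, so no p is given for these lists and the random lists serve as a reference alone.

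In 50 of 61 KRAB zinc finger genes with a peak in both replicates, of 84 in the list, the last exon was more covered than the rest of the gene, and in 10 it had no peak. Among those 10, Zfp229, Zfp445, Zfp950 and Zfp961 have short annotated last exons, 50 bp to 257 bp, against a median of 2649 bp over the 61 genes. In Zfp90 97.8% of the last exon and 53.5% of the rest of the gene lay under peaks, in Zfp180 92.6% and 33.7%, and in Zfp952 79.3% and 9.40%, the 3 most covered last exons. By contrast, Zfp160 had 0% and 12.98%, and Zfp445, with a last exon of 118 bp, 0% and 36.99%. The hypothesis was that last exons of these genes exceed those of other genes. Over the 61 genes the mean excess was 20.2 percentage points (30.6% against 10.4%), against 6.38 in random lists matched on last exon length (95% range 2.85 to 10.2; two-sided permutation p = 0.0002, the smallest the test can give). Another 212 Zfp genes had an excess of 20.2 points as well.

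Chromatin regulators were among the most covered of the later lists, with 26 of 37 marked and a mean of 18.7% ± 2.55 (SD, n = 2) against 3.22% in random lists, led by Kmt2d, Chd4, Trrap and Kmt2b (37.7% ± 4.83). Nuclear pore and transport genes had 19 of 27 marked (17.2% ± 2.40 against 4.16%), translation factors 15 of 25 (18.96% ± 2.54 against 4.72%, with Eif4g2 at 52.2% ± 4.17), proteasome subunits 15 of 27 (15.1% ± 1.55 against 4.78%), and motors and adaptors 9 of 25 (11.1% ± 1.23 against 2.70%, with Sptan1 at 34.98% ± 3.91). Receptors and effectors of Notch, Wnt, Hedgehog and Fgf signalling had 7 of 27 marked (7.95% ± 1.63 against 3.09%), with Axin2 at 21.4% ± 1.04. Respiratory chain subunits had 9 of 26 marked (11.9% ± 2.82 against 4.64%) and glycolysis enzymes 5 of 18 annotated genes, 2 of which carry the symbol Aldoa (8.81% ± 1.52 against 4.53%), with Pkm at 31.9% ± 7.30. Secreted patterning ligands had 0 of 24 marked (0.644% against 3.85%), keratin and epidermal genes 0 of 19 (0.0805% against 3.99%) and cytokines and immune receptors 0 of 20 (0.138% against 4.11%).

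Of 6028 long noncoding genes that overlap no protein-coding gene, 18 were marked. Gm26917 had 68.6% ± 7.60 (chromosome 17, 39843013 to 39846341) and its neighbour Gm42418 25.3% ± 4.44. Peaks were not screened for repeated sequence here, and the placing of reads at this pair of genes was not tested. The small nucleolar RNA host genes Snhg17 and Snhg1 had 37.2% ± 0.502 and 28.3% ± 0.119, Malat1 20.5% ± 9.57, and Mir17hg, host of a microRNA cluster, 19.3% ± 2.42.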
